A study of Bos taurus with 86 samples.

How the data were processed

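Single bovine embryos were profiled on 2-colour cDNA arrays in a reference design. The labels place 43 embryos in 3 groups: AI (14 embryos), IVD (14 embryos) and IVF (15 embryos). AI was read as artificial insemination and IVF as in vitro fertilization; the labels do not spell out IVD, and it is used here as a group name only. The developmental stage is not given in the sources used here. Per the labels' protocols, embryo RNA went through 3 rounds of linear amplification and the common reference RNA through 2 rounds, and each embryo was hybridised to 2 arrays with the dyes exchanged, which gives 86 arrays. The labels give each embryo its own number within its group. IVD embryos 12_1 to 12_4 share the first part of their number, and whether they have a common origin is not stated, so p-values for IVD measure the spread between embryos that may not all be independent.

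The values used are log2 ratios as deposited by the authors in a single table of 16416 rows and 86 columns. Image analysis, background correction and normalization are not given in the sources used here, nor is the rule by which spots were left without a value. Cells without a value made up 20.1% of the table (280751 empty cells, 3308 cells holding the word null, and 16 spots at a common ceiling that were set to missing). The array medians of the deposited log2 ratios ran from -2.22 to 1.06, so the arrays do not share a centre. The number of arrays limits the precision. No spot intensities were used here.

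The analysis plan, fixed before the data were examined, used the deposited values as given for the main results and median centring as an alternative. After the array medians had been seen, and before any group was tested, the 2 were exchanged: each array was centred on its median over the 5558 rows measured on every array, and the values as given became the alternative. On every embryo the 2 dye-swapped arrays were anticorrelated across rows (Pearson r between -0.912 and -0.589 in 43 of 43 embryos), so the deposited ratios run Cy5 to Cy3 or Cy3 to Cy5 throughout, and the arrays with the embryo in Cy3 were turned in sign. The labels do not say which of the dyes is the numerator. Cy5 over Cy3, which makes the turned values embryo over reference, was taken as likely from gene lists. The trophectoderm list had a median log2 ratio of 2.05 with 18 of 21 genes above 0. The list of cell junctions and blastocoel formation had a median of 1.57 (16 of 21 above 0). Medians were -2.09 for blood and immune cells (0 of 4 genes above 0), -0.837 for cumulus and granulosa cells (1 of 6), -0.0926 for oviduct and endometrium (0 of 3) and -0.425 for extracellular matrix and cytoskeleton (11 of 41). The plan asked for the maternal oocyte list to lie with the trophectoderm list, and it did not: its 2 measured genes had a median of -2.06. The plan's condition was therefore not fully met. With the opposite direction every sign below would turn. Each pair of higher and lower counts would change places, and each share of higher calls would become that of lower calls. Total counts of calls would stay.

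The ratios of an embryo's 2 arrays were averaged, so that each embryo is 1 replicate. A row was kept when at least 7 embryos of every group had a value on both arrays, which left 10757 rows. Row names came from the platform's annotation table, in which 11196 rows have 1 gene symbol and 190 have several, while 5030 rows are not listed there. Of the rows with 1 symbol, 11182 matched the RefSeq gene table of assembly ARS-UCD2.0 by gene identifier; no coordinates are given because the clones were not mapped. Rows with the same single symbol were averaged, and other rows stayed on their own as unnamed. This gave 6278 features, of which 3433 are named genes and 2845 are unnamed rows. In 5693 pairs of neighbouring rows with the same clone accession, the centred values correlated at r = 0.951 across spots.

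Groups were compared with limma 3.58.1 in R 4.3.3 (a linear model of group means over all embryos with empirical Bayes moderation, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). An F-test over the 3 means was fitted on the same values. Every adjusted p of a gene below is from limma, and errors beside differences are standard errors. Separation of whole profiles was tested by permutational analysis of variance on the 3711 features measured in every embryo with 100000 permutations, and the spread between embryos by permuting group labels over distances to the group mean. Of 30 gene lists fixed before the data were examined, the 24 with at least 5 measured members were tested with limma's camera (preset correlation 0.01, adjusted over the 24 lists), and again with a correlation estimated from the data. Figures were drawn with matplotlib 3.10.9.

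The genes named follow a rule fixed before the data were examined. Per comparison it takes the 12 highest and the 12 lowest changes among named genes past the threshold and up to 4 members of each list by size of change among those past the threshold. It also takes GATA3, KRT18, SLC2A1, IGF2R, SOD2 and PTGS2 where measured; other genes of that fixed set were not measured after filtering. Genes named outside this rule are marked as such.

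The fits were tested on simulated data with 200 changed features among 6278. For IVF against AI, 53% of features changed by 0.5 and 96% of those changed by 1 on the log2 scale were recovered. For IVD against AI the shares were 47% and 93%, and for IVF against IVD 57% and 93%. False calls made up 3.25%, 2.1% and 3.85% of the calls. In the list test, the 1 list that was moved was called and 0 of the other lists were. The simulated features were independent of each other, so this could not show false calls that come from correlation within a list. No embryos were counted as duplicates: the highest correlation across features between 2 embryos of a group was 0.923 in AI, 0.959 in IVD and 0.944 in IVF, which does not set any pair apart as identical.

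Alternatives fixed before the data were examined were the values as given, quantile normalization, each dye alone, all arrays in 1 fit with the embryo as random block, other row filters, each row on its own, array weights, robust moderation, only the groups compared, AI embryos H1, H3 and H5 left out, IVD embryos 12_1 to 12_4 averaged, the embryo number as a block, each embryo left out, stricter thresholds and an estimated list correlation. Alternatives chosen after seeing the data were centring on all measured rows, IVF embryos 1, 7 and 11 left out, a dye-bias score as covariate, the dye-bias cluster as a block, named genes only, and quantile normalization for the gene lists. The dye bias of an embryo is the part of its log2 ratios that does not change sign with the dye swap.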

Results

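Log2 ratios of single bovine embryos to a common reference RNA were available for 14 AI, 14 IVD and 15 IVF embryos. By the series title, the study asked how maturation, fertilization and culture in vitro affect the expression profile of single embryos. Per array, 10137 to 14119 rows were measured in AI, 13754 to 15618 in IVD and 10255 to 15300 in IVF. All values below are log2 differences between group means of embryo over reference, a direction that is likely rather than stated by the labels.

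The 3 groups formed separate profiles. In the plot of principal components, the leading component held 22% of the variance and placed IVD embryos (-25.7 to -14.6) apart from AI (1.06 to 12.6) and IVF (5.59 to 31.3). The second held 14.1% and placed AI (10.8 to 20.6) apart from IVF (-17.9 to -4.85). Group membership accounted for 33.4% of the variance of all 43 profiles (permutation p = 1e-05, the smallest that 100000 permutations can give). By pairs it accounted for 21.3% between IVF and AI, 29.5% between IVD and AI and 31.3% between IVF and IVD, each with an adjusted permutation p of 1e-05, again the smallest possible. Of 6278 features, 4214 differed among the groups in limma's F-test, 2399 of them named genes.

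**Figure D1:**
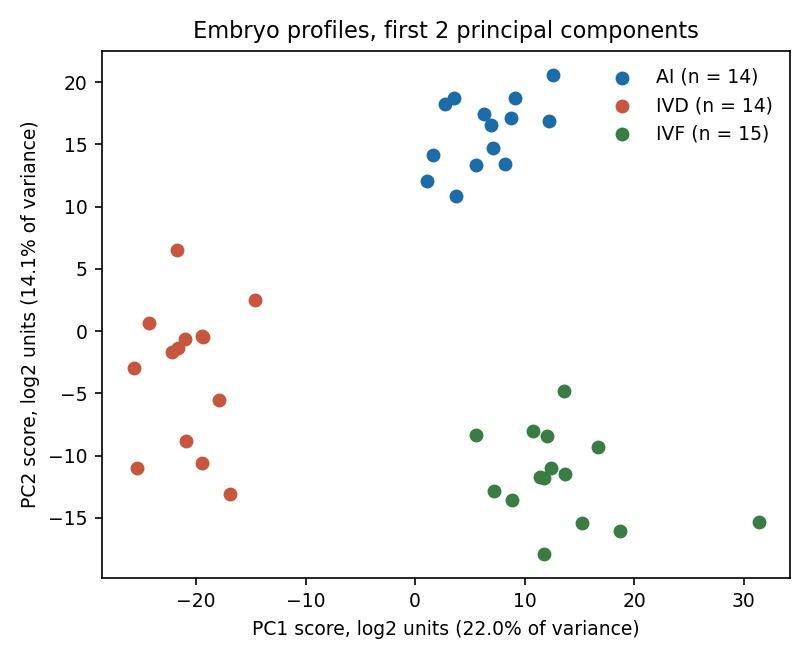
Scores of the 43 embryos (1 point each) on the leading 2 principal components of the centred log2 ratios, over 3711 features, in log2 units and coloured by group. IVD embryos lie at -25.7 to -14.6 on the horizontal axis, and AI embryos at 10.8 to 20.6 on the vertical axis, above all IVF embryos.

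The IVD arrays also stood apart in their technical measures. The embryo means of rows without a value were 1001.5 to 1871.5 in IVD, against 3613 to 5713 in AI and 3076.5 to 5099.5 in IVF. The correlation between an embryo's 2 arrays, with 1 turned in sign, was 0.589 to 0.767 in IVD, 0.816 to 0.912 in AI and 0.717 to 0.911 in IVF. No IVD embryo lay within the AI range of either measure. The correlation was taken over all rows with a value on both arrays, which are more in IVD, so it does not by itself rank the groups by noise. Over the 3711 features measured in every embryo, dye bias varied least between IVD embryos. The median technical SD it gives was 0.0708 in IVD, 0.154 in AI and 0.189 in IVF. This SD tells how alike the dye bias of a group's embryos is. It leaves out the rows not measured in every embryo, so it does not rank single arrays by noise either. The labels give no slide, day or batch.

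**Figure D2:**
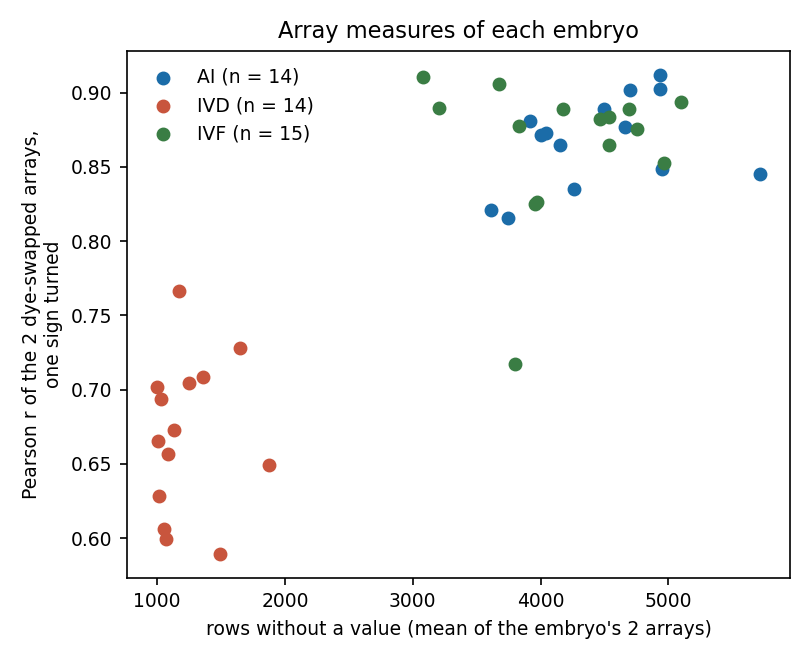
Rows without a value (mean of an embryo's 2 arrays, horizontal) against the Pearson correlation of its 2 dye-swapped arrays after turning 1 in sign (vertical), 1 point per embryo, coloured by group. IVD embryos lie at 1001.5 to 1871.5 rows, below all AI and IVF embryos.

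IVF embryos were compared with AI embryos, which contrasts embryos from fertilization in vitro with those from insemination. Maturation and culture in vitro, which the series title also names, cannot be separated from fertilization in this comparison. IVF embryos had lower ratios for genes of the respiratory chain, and genes of the stress lists went both ways. HMOX1, the haem-degrading enzyme induced by oxidative stress, was higher by 1.91 ± 0.29 (SE, limma adjusted p = 1.6e-06), and TXNRD1, a thioredoxin reductase, by 1.30 ± 0.15 (adjusted p = 9.23e-09). ATF4, the transcription factor of the amino acid response, was higher by 1.10 ± 0.19 (adjusted p = 1.22e-05). OCIAD2 showed the highest change of all named genes, 2.21 ± 0.39 or 4.61-fold (adjusted p = 2.26e-05), followed by FILIP1L at 2.17 ± 0.24 (adjusted p = 3.22e-09). The lowest were MPHOSPH8, a chromatin-binding protein, at -1.98 ± 0.37 (adjusted p = 7.91e-05), and ZCCHC17 at -1.95 ± 0.19 (adjusted p = 1.29e-10).

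In total 2365 features passed the threshold, 1251 higher and 1114 lower in IVF, with 688 named genes higher and 687 lower. Other high genes were TOMM34 (1.89), a cofactor of mitochondrial import, the Wnt receptor FZD4 (1.86), the small heat shock protein HSPB8 (1.70) and the urokinase gene PLAU (1.68). Among the lowest were the complement inhibitor CD59 (-1.79), the immediate early gene EGR1 (-1.76), the RNA-binding protein LARP7 (-1.71), GAR1 (-1.64) of small nucleolar ribonucleoproteins, the poly(A)-binding protein PABPN1 (-1.62), TOMM7 (-1.58) of the mitochondrial import complex and the chaperone HSP90AA1 (-1.52).

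Of the oxidative phosphorylation list, 33 of 39 measured genes were lower and 1 was higher in IVF, with a median change of -0.567. The counts adjusted over the list alone were 33 lower and 1 higher. COX7A2 of complex IV was lower by -1.31 ± 0.10, NDUFB9 of complex I by -1.10 ± 0.14, and UQCRQ of complex III by -1.03 ± 0.12. The list was called (camera adjusted p = 8.72e-13) and held with an estimated correlation (adjusted p = 0.00941). The embryos' own medians over this list were 0.318 ± 0.142 (SD, n = 14) in AI and -0.219 ± 0.166 (SD, n = 15) in IVF, and 15 of 15 IVF embryos lay below the lowest AI embryo.

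Of the ribosomal protein list, 27 of 45 genes were lower and 1 higher (31 lower and 1 higher adjusted over the list alone), with a median of -0.366; RPL35A changed by -1.30 ± 0.13 and RPL30 by -0.96 ± 0.15. The list was called (camera adjusted p = 1.08e-09), but not with an estimated correlation (adjusted p = 0.227). Of the mitochondrial ribosomal proteins, 17 of 36 were lower and 1 was higher (18 and 2 over the list alone), with a median of -0.293, MRPL51 at -1.03 ± 0.21 and MRPL24 at -0.90 ± 0.16. That list was called too (adjusted p = 4.02e-04), and not with an estimated correlation (adjusted p = 0.0896).

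The stress lists did not pass in camera. In the oxidative stress response list 7 of 22 genes were higher and 6 lower (the same over the list alone; camera adjusted p = 0.841), with HMOX1 and TXNRD1 on one side and the mitochondrial peroxidase PRDX3 (-1.004 ± 0.16) on the other. In the list of the amino acid response and ATF4 targets 5 of 12 were higher and 2 lower (5 and 2 over the list alone; median 0.397, adjusted p = 0.344), among them ATF3 at 1.23 ± 0.23, whose 3 clones differed in sign (-0.459 to 2.40 by row) and which was at 2.36 over rows measured in every embryo. In the list of heat shock and protein folding 5 of 22 were higher and 6 lower (the same over the list alone; adjusted p = 0.841), with the mitochondrial chaperonin gene HSPE1 at -0.98 ± 0.15 and HSP90AA1, given above, among the lower. Of the glycolysis genes 4 of 15 were higher and 4 lower (4 and 4 over the list alone; adjusted p = 0.837), with PFKFB3 (1.01), an activator of glycolysis, and LDHA (0.95) above and TPI1 (-0.78) below. The embryos' own medians over the glycolysis list were -0.652 ± 0.261 (SD, n = 15) in IVF and -1.005 ± 0.32 (SD, n = 14) in AI, with 0 of 15 IVF embryos below the AI mean; this difference was not tested apart from camera.

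With the values as given, 1325 features passed for IVF against AI (644 higher, 681 lower). The dye-bias profiles were cut into 3 clusters, a set number and an alternative chosen after seeing the data. The clusters held 13 AI, 14 IVD and 2 IVF embryos, 1 AI and 11 IVF embryos, and 2 IVF embryos. The block was fitted on AI and IVF embryos only. With the cluster as a block 504 features passed and 63 of the 152 called genes that the naming rule covers stayed past the threshold. Of those named above, the calls of OCIAD2, FZD4, HSPB8, MPHOSPH8, EGR1, ATF3, PFKFB3 and LDHA were lost (adjusted p from 0.0566 for PFKFB3 to 0.474 for MPHOSPH8). With the block, the values were 1.74 for OCIAD2, -1.51 for EGR1, 1.23 for ATF3, 0.90 for PFKFB3 and 0.86 for LDHA. Those of FZD4 (0.998), HSPB8 (0.74) and MPHOSPH8 (-1.30) moved by over 1.5 times, as did those of PLAU (1.07) and NDUFB9 (-0.73), which still passed. TOMM34 was at 1.16 on arrays with the embryo in Cy3 alone. Of the 2365 calls, 98.9% had the same sign with the block, and standard errors were 1.73 times as large at the median. The oxidative phosphorylation list had a median of -0.566 with the block (camera adjusted p = 3.02e-09 at the preset correlation of 0.01). Its estimated correlation was 0.142, and the block was not run with it, so this p may be too small. The blocked differences rest mainly on the 2 IVF and 1 AI embryos that lie in a cluster mostly of the other group.

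IVD embryos were compared with AI embryos. The highest change of any named gene was that of PSPH, the last enzyme of serine synthesis, at 3.65 ± 0.29 or 12.6-fold (limma adjusted p = 2.9e-13), followed by OCIAD2 at 3.40 ± 0.40 or 10.6-fold (adjusted p = 3.48e-09) and the tight junction gene CLDN1 at 2.60 ± 0.50 (adjusted p = 3.86e-05). The mTOR inhibitor DDIT4 (1.64 ± 0.24) and the p53 regulator MDM2 (1.64 ± 0.32) were also higher. The lowest were MCM2 of the replicative helicase at -2.15 ± 0.25 (adjusted p = 3.16e-08), ALAD of haem synthesis at -1.80 ± 0.15 (adjusted p = 5.86e-13) and TUBGCP2 of the gamma-tubulin complex at -1.79 ± 0.16 (adjusted p = 3.74e-11). CLDN1 was at 1.64 on arrays with the embryo in Cy3 alone, 1.45 with it in Cy5 alone and 1.53 with rows kept at 2 embryos per group, and TUBGCP2 at -1.18 with Cy3 alone; all passed.

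In total 2921 features passed, 1603 higher and 1318 lower (54.9% higher), with 849 named genes higher and 802 lower. With the values as given the median of all features was 0.317, against 0.0579 with centring. Then 2819 features passed, of which 2405 were higher and 414 lower (85.3% higher). The share of higher calls therefore rests on the centring, and also on the direction of the ratios. This share was 65.1% on arrays with the embryo in Cy3 and 45.5% on arrays with it in Cy5.

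The 3 lists called for IVF against AI were called in IVD against AI as well. Both comparisons use the same AI embryos, so this is no independent repeat. Of the oxidative phosphorylation list, 24 of 39 were lower and 1 higher (25 and 2 over the list alone), with a median of -0.439, and NDUFV1 (-1.54 ± 0.14) and NDUFA10 (-1.16 ± 0.18) of complex I and SDHA (-1.16 ± 0.17) of complex II as examples. The list was called (camera adjusted p = 1.15e-07), but not with an estimated correlation (adjusted p = 0.149). With the values as given its median was -0.185, where the median of all features was 0.317. Embryo medians over the list were -0.204 ± 0.144 (SD, n = 14) in IVD, with 14 of 14 below the lowest AI embryo. Of the ribosomal proteins 21 of 45 were lower, led by RPS2 (-1.60), and 7 higher (21 and 8 over the list alone), with a median of -0.213 (adjusted p = 0.001, and an adjusted p of 0.689 with an estimated correlation). This median turned to 0.0408 with the values as given. Of the mitochondrial ribosomal proteins 17 of 36 were lower, led by MRPS12 (-1.74 ± 0.15), and 2 higher (17 and 2 over the list alone), with a median of -0.284 (adjusted p = 0.0256, and an adjusted p of 0.362 with an estimated correlation); with the values as given the median was -0.0294. On arrays with the embryo in Cy5 alone neither ribosomal list passed (adjusted p = 0.151 for both, over a range of 4.38e-07 to 0.689 for ribosomal and 0.00354 to 0.362 for mitochondrial ribosomal proteins in 8 alternatives).

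Glycolysis genes were lower in IVD, 10 of 15 with 4 higher (11 and 4 over the list alone) and a median of -0.463 (camera adjusted p = 0.0304). With an estimated correlation the adjusted p was 0.319. The median was -0.225 with the values as given and -0.648 with quantile normalization. The aldolase ALDOA (-1.41 ± 0.15) and the enolase ENO1 (-1.22 ± 0.20) were lower. The list did not pass on arrays with the embryo in Cy5 alone (adjusted p = 0.317) or with the embryo number as a block (adjusted p = 0.0556), in a range of 0.000767 to 0.319 over 8 alternatives. The embryos' own medians over this list overlapped: -1.09 ± 0.138 (SD, n = 14) in IVD and -1.005 ± 0.32 (SD, n = 14) in AI, with 0 of 14 IVD embryos below the lowest AI embryo.

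In the trophectoderm list 8 of 21 genes were higher and 5 lower in IVD (the same over the list alone; camera adjusted p = 0.58). The transcription factor TFAP2C (1.04 ± 0.17) and the prostaglandin synthase PTGS2 (1.03 ± 0.14) were higher and SSLP1 (-1.12 ± 0.35) lower. In the list of cell junctions 9 of 21 were higher and 5 lower (9 and 5 over the list alone; adjusted p = 0.517), with the epithelial adhesion genes CDH1 (1.16 ± 0.12) and EPCAM (1.05 ± 0.13) above and DSC2 (-1.09 ± 0.26) below. In the oxidative stress response list 7 of 22 were higher and 4 lower (7 and 5 over the list alone; adjusted p = 0.595), among them SOD1 (1.54 ± 0.19) and TXN (1.21 ± 0.16) above and SOD2 (-0.92 ± 0.17) below. With quantile normalization the value of PTGS2 was 0.24 and did not pass (adjusted p = 0.0858, in a range of 1.49e-09 to 0.0858 over 14 alternatives). CDH1 was at 0.49 and TFAP2C at 0.69 with it, TFAP2C at 0.62 on arrays with the embryo in Cy5 alone and SOD2 at -0.61 with the embryo number as a block, and these passed. The rows of the 2 TFAP2C clones ran from 0.317 to 2.00. The IVD embryos all lie outside the AI range of rows without a value and of dye-swap correlation. Array handling and group therefore cannot be told apart for these differences.

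**Figure D3:**
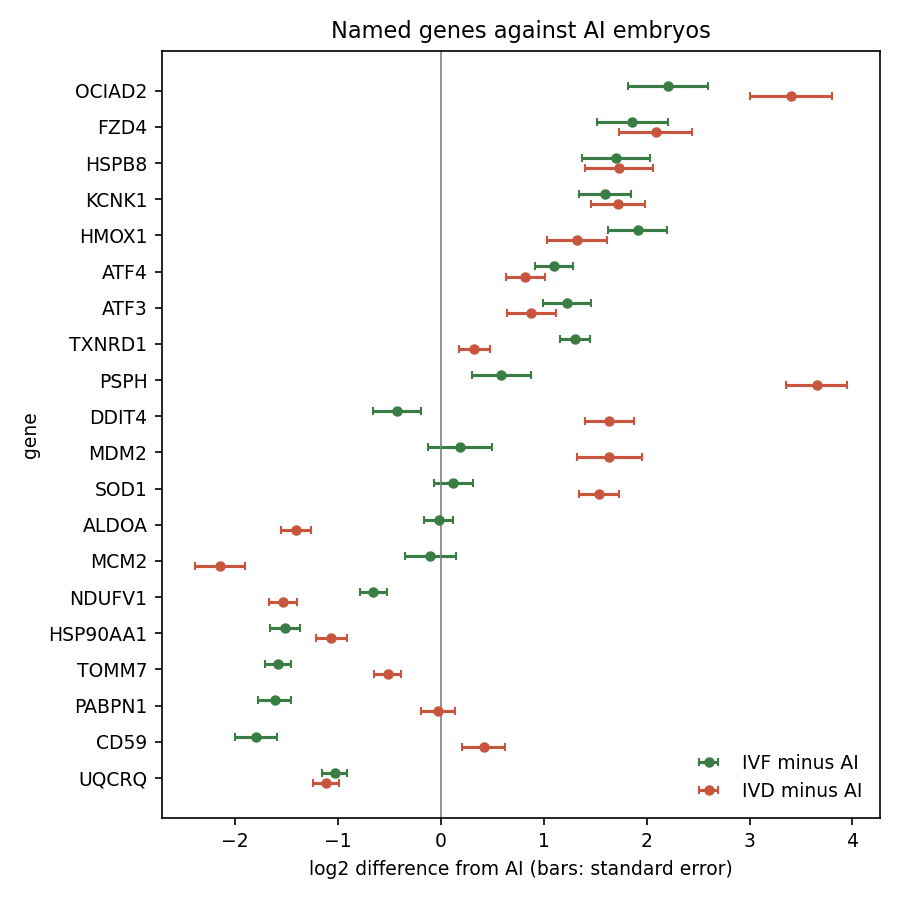
Log2 differences from AI embryos for 20 named genes, IVF minus AI and IVD minus AI, as points with standard errors. OCIAD2 lies at 2.21 and 3.40 and HSP90AA1 at -1.52 and -1.06.

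IVF embryos were compared with IVD embryos. MCM2 was higher in IVF by 2.04 ± 0.22 (limma adjusted p = 5.75e-09), DPP3 by 1.73 ± 0.17 (adjusted p = 2.42e-11) and the chaperone DNAJA3 by 1.69 ± 0.20 (adjusted p = 3.3e-09). PSPH was lower by -3.06 ± 0.29 (adjusted p = 1.36e-11), CD59 by -2.21 ± 0.20 (adjusted p = 6.42e-12) and DDIT4 by -2.06 ± 0.23 (adjusted p = 1.4e-09). The kinase AKT1 (1.48 ± 0.14) was higher. In the list of cholesterol and fatty acid synthesis 4 of 7 were higher and 0 lower (4 and 0 over the list alone), among them LSS (1.59 ± 0.23) and FDPS (1.48 ± 0.22), and the list did not pass (camera adjusted p = 0.11, and an adjusted p of 0.493 with an estimated correlation). It passed on arrays with the embryo in Cy3 alone (adjusted p = 0.0391) and with the values as given (0.0394).

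In total 2986 features passed, 1403 higher and 1583 lower in IVF (47% higher). With the values as given 2663 passed, 465 higher and 2198 lower (17.5% higher). The median of all features was then -0.266, against -0.00884 with centring. The share of higher calls was 33.6% on arrays with the embryo in Cy3 and 61.3% on arrays with it in Cy5, so this split has no settled majority. It would also turn with the direction of the ratios. The IVD embryos lie below all IVF embryos in rows without a value, so array handling and group cannot be told apart for these differences either. Of the 24 lists 0 passed in limma's camera, and 5 had an unadjusted p under 0.05. The nearest was glycolysis, with 7 of 15 higher and 2 lower (9 and 2 over the list alone), a median of 0.389 and an adjusted p of 0.0516 (an adjusted p of 0.364 with an estimated correlation). It passed on arrays with the embryo in Cy3 alone (adjusted p = 0.00131), with the values as given (0.0266), with quantile normalization (0.0179), with centring on all measured rows (0.0483) and without IVF embryos 1, 7 and 11 (0.0155). Its ENO1 (1.44 ± 0.19) and ALDOA (1.39 ± 0.14) were higher. Oxidative phosphorylation genes were divided between these groups, 9 of 39 higher and 14 lower (10 and 15 over the list alone; adjusted p = 0.851).

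**Figure D4:**
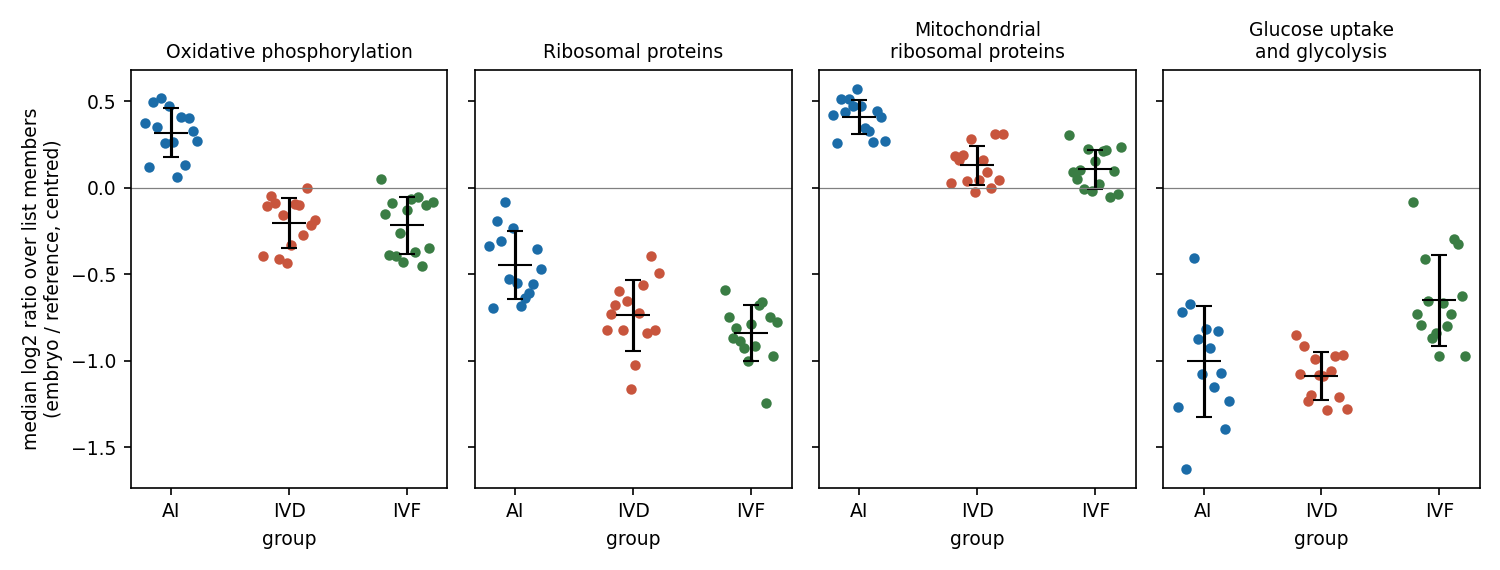
Median log2 ratio of each embryo over the members of 4 gene lists (1 point per embryo, black marks give the mean and SD of a group). For oxidative phosphorylation, AI embryos lie at 0.061 to 0.517, above all IVD (-0.437 to -0.00325) and IVF (-0.453 to 0.0515) embryos; for glycolysis the groups overlap.

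Of the genes fixed for naming whatever their result, KRT18, a keratin of the trophectoderm, was at -0.36 ± 0.12 in IVF against AI (limma adjusted p = 0.0134), and the glucose transporter SLC2A1 at -0.42 ± 0.17 (adjusted p = 0.0408). Both calls were lost in several alternatives, with adjusted p from 0.00131 to 0.256 for KRT18 and 0.0053 to 0.385 for SLC2A1. In IVD against AI neither passed (-0.22 ± 0.12 and -0.38 ± 0.17), though each did in some alternatives (lowest adjusted p 0.00257 and 0.00806). In IVF against IVD the transcription factor GATA3 was at -0.56 ± 0.24 (adjusted p = 0.0486, in a range of 6.57e-14 to 0.727 over the alternatives) and the imprinted receptor gene IGF2R at 0.36 ± 0.11 (adjusted p = 0.00806, in a range of 0.000159 to 0.644), and the 2 clones of each differed in sign. Over the alternatives GATA3 ran from -1.51 to -0.10 and IGF2R from 0.09 to 0.71. Against AI neither passed, with GATA3 at -0.11 ± 0.24 in IVF and 0.45 ± 0.24 in IVD, and IGF2R at 0.12 ± 0.11 and -0.24 ± 0.12. In IVD both passed in some alternatives (lowest adjusted p 7.31e-11 for GATA3, at 1.21 over rows measured in every embryo, and 0.00225 for IGF2R), and GATA3 did in IVF over those rows (-0.30, adjusted p = 0.0399). SOD2 was at 0.07 ± 0.17 in IVF against AI and PTGS2 at 0.12 ± 0.14, and neither passed. In IVF against IVD SOD2 was higher by 0.99 ± 0.17 (adjusted p = 5.22e-06) and PTGS2 was at -0.91 ± 0.14 (adjusted p = 6.68e-07), or -0.035 with quantile normalization (adjusted p = 0.823).

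IVF and IVD were both compared with the same AI embryos. In both groups 569 features were higher and 449 lower than in AI, and 266 moved in opposite directions, where independent lists would share 319 higher, 234 lower and 547 opposite. Shared named genes numbered 308 higher, such as OCIAD2, FZD4, HSPB8, KCNK1 and HMOX1, and 284 lower, such as HSP90AA1, UQCRQ and AIFM1; in IVF the calls of OCIAD2, FZD4, HSPB8, KCNK1 and AIFM1 were among those lost with the dye-bias cluster as a block. The changes correlated at r = 0.384 across features, which are not independent replicates, and 62% had the same sign. Unchanged groups simulated against the same AI embryos gave r = 0.518 and 67.2% from the shared comparator alone. Real group differences change both values, so neither can tell whether IVF and IVD share a response beyond that comparator. The covariance was 0.0984 against 0.0179 simulated, a difference of 0.0805. With the AI embryos split 7 and 7, 203 higher and 193 lower features were shared, where independent lists would share 126 and 113, with a covariance of 0.0746, r = 0.268 and 59.1% of the same sign. With these sets of AI embryos exchanged 280 and 236 were shared, where independent lists would share 154 and 133, with r = 0.271 and 58.97% of the same sign.

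The spread between embryos was measured as the distance of each embryo to its group's mean profile. It was 0.464 ± 0.0561 (SD, n = 14) in AI, 0.407 ± 0.0668 (SD, n = 14) in IVD and 0.460 ± 0.130 (SD, n = 15) in IVF. No difference passed: the adjusted permutation p was 0.0655 for IVD against AI, 0.28 for IVF against IVD and 0.919 for IVF against AI. The IVD against AI difference was -0.0569 here and passed with the values as given (-0.124, adjusted permutation p = 0.00054) and with either dye alone. It was -0.036 without AI embryos H1, H3 and H5 (adjusted permutation p = 0.28) and -0.029 with the technical variance subtracted (adjusted permutation p = 0.71). The median SD of a feature was 0.368 in AI, 0.324 in IVD and 0.4004 in IVF, and with the technical variance of the dye swaps subtracted 0.323, 0.313 and 0.334.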

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

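The alternatives that centre on all measured rows, leave out IVF embryos 1, 7 and 11, add a dye-bias score or cluster, keep named genes only, or apply quantile normalization to the lists were chosen after seeing the data. The separation of the groups passed under each alternative run for it, and leaving out each embryo in turn gave 2246 to 2407 calls for IVF minus AI, 2770 to 2988 for IVD minus AI, 2875 to 3017 for IVF minus IVD and 4105 to 4225 in the F-test. Counts within 1.5 times the reported one ran from 1606 to 2485 in 14 of 21 alternatives for IVF minus AI, 2053 to 3262 in 14 of 18 for IVD minus AI, 2206 to 3472 in 15 of 19 for IVF minus IVD and 3392 to 4613 in 13 of 15 for the F-test. The oxidative phosphorylation list passed for IVF minus AI in 11 of 11 alternatives (medians -0.685 to -0.536). Where an alternative tests other features, sets a stricter threshold, uses fewer embryos or averages embryos, its construction changes the count or the spread. The values as given also keep the differences between array centres, and a single dye keeps the dye bias, which can add to the spread. For the other differences below the cause was not tested. No spot intensities were used, so how far signals lie over background is unknown.

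Calls of genes moved as follows. The values as given gave 1325 for IVF minus AI. Rows measured in every embryo (3533 features) gave 1571, 1770, 1880 and 2589 for IVF minus AI, IVD minus AI, IVF minus IVD and the F-test, and each row on its own (10757 rows) gave 4100, 4963, 5131 and 7235. A threshold of 0.01 gave 1472 for IVF minus AI. A change of at least 1.5-fold gave 1057, 1540 and 1672 for the 3 pairs, and named genes only gave 1413, 1664 and 1727. The dye-bias cluster as a block gave 504 for IVF minus AI. Features shared by IVF and IVD numbered 396 with the AI embryos split.

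Lists called moved to 3 for IVF minus IVD with Cy3 alone. With Cy5 alone they were 5, 1 and 2 for the 3 pairs, and 2 for IVF minus IVD with the values as given. Quantile normalization, centring on all rows and leaving out IVF embryos 1, 7 and 11 each gave 1 for IVF minus IVD. With an estimated correlation 1 list was called for IVF minus AI and 0 for IVD minus AI. Calls were lost with Cy5 alone for IVD minus AI, with medians of -0.462 for glycolysis, -0.262 for ribosomal and -0.363 for mitochondrial ribosomal proteins. An estimated correlation ended the calls of ribosomal (-0.366) and mitochondrial ribosomal proteins (-0.293) for IVF minus AI. It also ended those of glycolysis (-0.463), oxidative phosphorylation (-0.439), ribosomal (-0.213) and mitochondrial ribosomal proteins (-0.284) for IVD minus AI.

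Spread between embryos passed for IVD minus AI with the values as given (-0.124), Cy3 alone (-0.0954), Cy5 alone (-0.0942) and IVD embryos 12_1 to 12_4 averaged (-0.0833), and for IVF minus IVD with the values as given (0.162) and Cy3 alone (0.0959). It did not pass for IVD minus AI without AI embryos H1, H3 and H5 (-0.036) or with the technical variance subtracted (-0.029), and the latter turned IVF minus IVD to -0.00228.

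The labels give the groups shared embryo numbers, but same-numbered embryos did not clearly resemble each other. Their deviations correlated at -0.0148 on average for AI and IVF (7 pairs, 0 over 0.1) and -0.0182 for AI and IVD (5 pairs, 0). For IVD and IVF the average was 0.0127 (9 pairs, 2). With so few pairs this cannot show that the numbers carry no meaning. With the number as a block, on the 8 AI, 10 IVD and 12 IVF embryos that share one, 1606, 2053, 2514 and 3392 features passed, and glycolysis no longer passed for IVD minus AI (-0.627, adjusted p = 0.0556).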

Other observations

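Beyond the lists described above, imprinted genes moved in both directions. In IVD against AI, 5 of 13 were higher and 4 lower (the same adjusted over the list alone; limma camera adjusted p = 0.759), with NAP1L5 (1.15 ± 0.20) and MEST (0.83 ± 0.17), both paternally expressed in mammals, above, and GNAS (-0.80 ± 0.16) below; the GNAS call was lost with the values as given (adjusted p = 0.0619, in a range of 1.36e-06 to 0.0619 over 13 alternatives). In IVF against AI 2 were higher and 1 lower (2 and 1 over the list alone; adjusted p = 0.837). In the list of DNA methylation and chromatin regulators 6 of 16 genes were lower in IVF, 0 were higher (6 and 0 over the list alone) and 10 did not pass. Among the lower were the histone variant H2AZ1 (-1.02 ± 0.11) and HAT1 (-0.69 ± 0.16). The list did not pass (median -0.211, adjusted p = 0.0704, and an adjusted p of 0.227 with an estimated correlation). It passed with the values as given (adjusted p = 0.0291), on arrays with the embryo in Cy5 alone (0.0307) and with the dye-bias cluster as a block (0.0372). Splicing genes were 12 of 32 lower and 3 higher (13 and 3 over the list alone; median -0.218, adjusted p = 0.115), with U2AF1 at -0.81 ± 0.15. In IVF against IVD, the interferon-stimulated list had 4 of 6 genes higher and 0 lower (5 and 0 over the list alone; adjusted p = 0.11), led by TAP1 (1.10 ± 0.17, and 0.70 on arrays with the embryo in Cy3 alone), and the proteasome list had 4 of 25 higher and 7 lower (4 and 7 over the list alone; adjusted p = 0.598), led by PSMA4 (-1.59 ± 0.16).

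The lists of other cell types and tissues with at least 5 genes did not pass. In IVF against AI the trophectoderm list had 3 of 21 higher and 4 lower (the same over the list alone; camera adjusted p = 0.887), cell junctions 3 of 21 higher and 5 lower (the same over the list alone; adjusted p = 0.841), and extracellular matrix and cytoskeleton 4 of 41 higher and 8 lower (3 and 8 over the list alone; adjusted p = 0.85). Cumulus and granulosa cell genes had 4 of 6 higher and 0 lower (4 and 0 over the list alone), with HSD3B1 at 1.03 ± 0.34 (adjusted p of the list = 0.141). The HSD3B1 call was lost with the dye-bias cluster as a block (0.40), without AI embryos H1, H3 and H5 (0.89) and with the embryo number as a block (1.18), with adjusted p from 0.00209 to 0.654 over 16 alternatives. In IVD against AI the extracellular matrix list had 11 of 41 higher and 11 lower (12 and 11 over the list alone; adjusted p = 0.749), and the cumulus list 1 of 6 higher and 1 lower (the same over the list alone; adjusted p = 0.759). Lists under 5 genes were not tested: the median change was 0.114 in IVF and -0.403 in IVD for 4 blood and immune genes, -0.0643 and -0.128 for 3 oviduct and endometrium genes, and -0.104 and 0.246 for 2 maternal oocyte genes.

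The tests on oxidative phosphorylation genes, on the IVD arrays and on genes far below the reference were chosen after these patterns had been noticed; what each would show was written before its value was computed, though for the lists matched on level after the slight trend of the changes on that level had been seen. In 100 splits of the same embryos, the real one included, 1 gave as many calls as the real groups in each case, the least possible. Random grouping of the embryos is thus unlikely to give such counts, though single calls may still be false. There were 2365 calls for IVF and AI against 45 at most in the others, and 2921 against 825 for IVD and AI. For IVF and IVD there were 2986 against 956, and in the F-test 4214 against 2.

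The oxidative phosphorylation genes were lower in IVF than in AI. The first test of ratio compression removed the trend of the changes on the level in IVD embryos. The list's median residual was -0.578 (bootstrap SE 0.058). The trend was slight (slope -0.0522), so removing it could hardly move the list and this test decides nothing. Ratio compression would move genes of one level alike. Of 10000 random lists matched on the level in IVD embryos, 0% had a median as low as -0.567. The lowest was -0.273 and the middle of their medians 0.0242, so genes of that level did not move as the list did. Of as many lists matched on genomic length 0% had a median as low, with -0.401 as the lowest and -0.0356 in the middle. The middle values of 0.0242 and -0.0356 show that genes of that level or genomic length did not move as the list did. They argue against either alone as the cause, though transcript length was not available. The list was picked from these data for its low values, so few matched lists could be as low. Its genes are also correlated (0.142), unlike random ones, and the 0% is not a p-value. With the dye-bias cluster as a block the difference of embryo medians was -0.443 ± 0.0915 (SE) against -0.537 ± 0.0577 without it. It was -0.508 within the cluster of 13 AI and 2 IVF embryos. In the cluster of 1 AI and 11 IVF embryos it was -0.321, which rests on 1 AI embryo. The blocked difference argues against handling that these clusters capture as the whole cause. It rests mainly on the 2 IVF and 1 AI embryos that lie in a cluster mostly of the other group. Handling that the clusters do not capture stays open. Embryo medians over the list were low in IVD too (-0.204, against -0.219 in IVF and 0.318 in AI), so the pattern is not particular to IVF. A difference in respiratory chain transcripts between AI and IVF embryos may be biological, as a hypothesis.

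The IVD profiles differ from AI both in genes and in array measures. If separate handling of the arrays made the difference, AI embryos with a more IVD-like dye bias should have more IVD-like ratios; over the 14 AI embryos, Pearson's r was -0.385 (permutation p = 0.174, adjusted 0.174 over 2 tests) and Spearman's rho -0.464 (permutation p = 0.0979, adjusted 0.174), and r was -0.232 without the 2 embryos farthest from the median. This decides nothing, since no AI embryo reaches the IVD range of dye bias (r with the mean IVD profile up to 0.631 in AI, from 0.811 in IVD), and handling and group cannot be told apart. A biological difference between IVD and AI embryos was not tested apart from it.

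Single genes far below the reference, such as COL3A1 (-1.46 ± 0.11) and VIM (-1.07 ± 0.08), were lower still in IVD than in AI. Such genes were not lower as a set. A wider ratio range on the IVD arrays was tested on genes chosen by their level in IVF embryos. Over the 55 named genes under -3 the median change was 0.0953, with an SE of 0.119 over genes and 0.0756 over embryos. Of these, 13 were lower and 13 higher, where of all 3433 named genes 802 were lower and 849 higher. Over the 99 genes above 2 the median was 0.378 with 43 higher and 16 lower. The median at the lower end lay above the limit of -0.1 set beforehand by more than either SE, though by less than 2 SE over genes, which argues against a wider range as the whole cause of the lower values there; the comparison with its SE was added after the median had been seen. The upper end went with a wider range. For the single lower genes at the lower end, other technical causes, such as background, and a biological difference were not tested and stay open.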
